A study of Mus musculus with 17 samples.

How the data were processed

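Ribosome-bound RNA of astrocytes was compared across ONH (6 libraries), ONP (6 libraries) and CC (5 libraries) of untreated mice. Per the labels' protocols, tissue was micro-dissected, tagged ribosomes were isolated with an antibody to haemagglutinin on magnetic beads, mRNA was captured by its poly(A) tail, and libraries were made with a low-input Smart-Seq kit. Whether counting used strand was not given in the sources used here. The authors deposited a table of whole-number counts per Ensembl gene, not scaled, for the 17 libraries. They also deposited a second table of variance-stabilised values on a scale close to log2, in which every gene at 0 counts has the value 3.56 in every library. Per the submitters' processing notes, STAR 2.6.1d, Salmon 0.14.2, R 4.1.0, DESeq2 1.34.0 and the genome build mm10 were used; which of them gave the counts was not given in the sources used here. The table lists 28739 genes, each with a total of at least 1 count.

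Libraries were grouped by the region in their titles, which the columns of both tables repeat. The tissue entry of the CC samples names the optic nerve proper, and it was not used. Each ONH or ONP replicate is a pool of 4 mice per the labels. Whether replicates, or the ONH and ONP pools of a number, come from separate mice was not given in the sources used here, so p-values measure only the spread between these samples, which may in part be technical. The numbers that ONH, ONP and CC libraries share did not enter the tests of genes and lists, except as the block named among the alternatives. A relation of lens genes between ONH and ONP, given in the closing part, did set libraries of a number side by side. No library was a near copy of another of its region, since the lowest chi-square per degree of freedom between libraries of a region was 21.4, and pairs across regions were not tested.

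Totals lay between 15788103 and 30585626 counts per library. Intervals and floors cover counting error only, since no molecular identifiers were named in the sources used here. A region with 0 counts for a gene was set at a floor of 3 counts over the region, giving a bound on the fold. A region with 1 to 3 counts was given a ratio with an exact 95% counting interval.

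Counts were analysed in R 4.3.3 with edgeR 4.0.16, using TMM factors, filterByExpr by region (16055 genes tested, at least 99.87% of each library's counts), robust glmQLFit and the quasi-likelihood F test, two-sided. All 17 libraries entered a single fit with region as the term, and the 3 regions were compared by contrasts. P-values were adjusted by the Benjamini-Hochberg method over the genes tested, with a threshold of 0.05. Standard errors are the size of the log2 fold change divided by the square root of F, and are approximate. CPM values are TMM-normalised. A gene set a region apart when it was past the test in the same direction against both other regions. The count of such genes with no effect was taken from 20 simulated data sets. The count for independent lists, and the counts with the region's libraries split between its comparisons, were computed beside it. Libraries labelled male and female were compared in CC, and age (11 to 12 against 7 to 8 weeks) with region as a second term in 10 optic nerve libraries, with an interaction test. The 2 libraries of mice aged 9 to 10 weeks did not enter the age test.

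Gene lists, 25 in all, were tested with camera of limma 3.58.1 on voom values with a preset correlation of 0.01, at least 3 measured members, and adjustment over the 25 lists. They held markers of astrocytes, oligodendrocytes, oligodendrocyte precursors, microglia and macrophages, vascular cells, fibroblasts and meninges, neurons, photoreceptors, Muller glia, pigment cells, ependyma and choroid plexus, and the neurogenic niche. The functional lists were forebrain transcription factors, eye and optic stalk transcription factors, extracellular matrix and basement membrane, transmitter uptake and potassium handling, cholesterol synthesis, respiratory chain, cytosolic ribosomal proteins, a reactive astrocyte panel, antigen presentation and interferon response, immediate early and stress response, engulfment, Hedgehog, Wnt and BMP signalling, and glaucoma-associated genes. Members were counted by the test over all genes, and the count adjusted over the list alone is given where it differs. Of the 18 astrocyte markers 6 belong to another list too, as do 6 of 25 glaucoma-associated genes, 5 of 20 uptake genes, 4 of 36 reactive panel genes and 4 of 11 eye factors.

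Groups, tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined. For each region comparison the rule took the 6 genes with the largest and the 6 with the smallest log2 fold change, among those past the test with a mean of at least 10 CPM in the higher region and no overlap between libraries. It added, from each of the 6 lists with the lowest camera p, the 2 members that changed most in the list's direction with at least 5 CPM, and a panel of 8 genes (Gfap, Aqp4, Slc1a2, Slc1a3, Gja1, Aldh1l1, Pax2 and Foxg1). For genes that set a region apart it took the 5 with the largest smaller change in each direction, and for sex and age at most 4 genes each way. Genes named by other routes are said to be chosen after their values were seen, except Ddx3y and Xist, which were named to check the sex labels. Predicted genes without a name were counted and not named.

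Gene extents came from the GENCODE M21 annotation of GRCm38, the same assembly as mm10, 1-based. Gene types came from the deposited count table, and the genes given with coordinates are protein-coding. Exons of named genes were checked for overlap. Named genes that shared more than 10% of exon length with another gene were Dhh, Slc7a10, Foxg1, Vxn, Psmb8, Cryaa and Aldh1l1, and their counts are uncertain to that extent, as are those of the crystallin, H2 and ribosomal protein families, whose members or pseudogenes resemble each other.

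Alternatives were RLE and upper-quartile factors, DESeq2 1.42.0 (Wald test), limma voom with quality weights, limma-trend on the deposited variance-stabilised values, no low-count filter, a filter of at least 1 CPM in at least 5 libraries, the 2 regions alone, the 2 regions with the replicate number as a block, libraries of 7 to 8 weeks alone, the age band as a covariate, an estimated correlation for camera, and leaving out each library in turn. After the data were seen, fits without both optic nerve libraries numbered 5 and with the mean oligodendrocyte marker level as a covariate were added, as was a list of 15 lens genes.

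The procedure was tested on simulated counts in which 200 genes were changed. For ONH against ONP, edgeR recovered 55% of 2-fold and 90% of 4-fold changes, with 4.61% of its calls false among 15812 genes. For ONH against CC the values were 51%, 85% and 5.56% among 15808 genes, and for ONP against CC 54%, 89% and 5.30% among 15786 genes. DESeq2 had 15.9%, 19.4% and 21.8% false calls in the 3 comparisons, and limma voom 4.05%, 4.32% and 4.08%. For age, edgeR recovered 40% of 2-fold and 71% of 4-fold changes among 15969 genes, for the interaction 0% and 28% among 15959 genes, and for CC libraries by sex label 0% and 39% among 15574 genes. Reads were not analysed here, and strand, duplicates and mapping could not be checked.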

Results

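RNA bound to the ribosomes of astrocytes was measured in 3 white matter tracts of untreated mice, namely the optic nerve head (ONH), the optic nerve proper (ONP) and a tract that the labels call CC without spelling the name out. The mice carried RiboTag, an allele of the ribosomal protein gene Rpl22 that gains a haemagglutinin epitope when Cre recombinase acts on it, and a Cre transgene under the GFAP promoter. Tagged ribosomes were pulled down with an antibody to the epitope, and the mRNA they carried was sequenced. There were 6 ONH, 6 ONP and 5 CC libraries. Per the labels, each ONH or ONP library held tissue of 4 mice, 2 of them male and 2 female, aged between 7 and 12 weeks. Xist, expressed from the inactive X chromosome, went against this in ONH replicate 4 and ONP replicate 4, where it was 0 CPM (counts scaled to the library total) beside 0.685 to 3.90 in the other optic nerve libraries. The Y-linked gene Ddx3y stood at 69.5 and 76.8 CPM in ONH and ONP replicates 4. It ran from 32.15 to 78.52 CPM in the other optic nerve libraries, so it did not set replicates 4 apart. The CC mice were 7 to 8 weeks old, and the number of mice in a CC library was not given in the sources used here. The CC libraries were grouped by their titles, because the tissue entry of those samples names the optic nerve proper. Total counts per library lay between 15917700 and 29460336 in ONH, between 15788103 and 30585626 in ONP, and between 15969273 and 18392169 in CC.

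CC libraries stood apart from both optic nerve regions, and ONH stood closer to ONP. Across 16055 tested genes, the median correlation of log2 CPM was 0.923 between ONH and ONP libraries, 0.788 between ONH and CC, and 0.832 between ONP and CC, against 0.939, 0.950 and 0.968 within ONH, ONP and CC. The first principal component, with 53.7% of the variance, separated CC from the optic nerve. The third, with 7.07%, set ONH replicate 5 and ONP replicate 5 apart from the rest, at -78.7 and -78.2. In the same 2 libraries microglial markers took 0.0379% and 0.0443% of the counts, compared with means of 0.229% ± 0.103 in ONH (SD, n = 6) and 0.284% ± 0.133 in ONP (SD, n = 6).

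Transcripts that mark cells other than astrocytes were present in every region and in different proportions. Whether they came from those cells or from the astrocytes themselves is not settled by these counts. Oligodendrocyte markers held 5.79% ± 2.21 of the counts in ONH, 10.1% ± 3.21 in ONP and 6.49% ± 1.06 in CC (SD, n = 6, 6 and 5 here and in the rest of the text). Microglial and macrophage markers held 0.0131% ± 0.00359 in CC, below every optic nerve library. Neuron markers ran the other way, with 0.160% ± 0.0673 in CC, 0.0150% ± 0.00507 in ONH and 0.00887% ± 0.000878 in ONP. Photoreceptor markers held 0.0541% ± 0.0394 in ONH and 0.00633% ± 0.00383 in ONP.

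**Figure D1:**
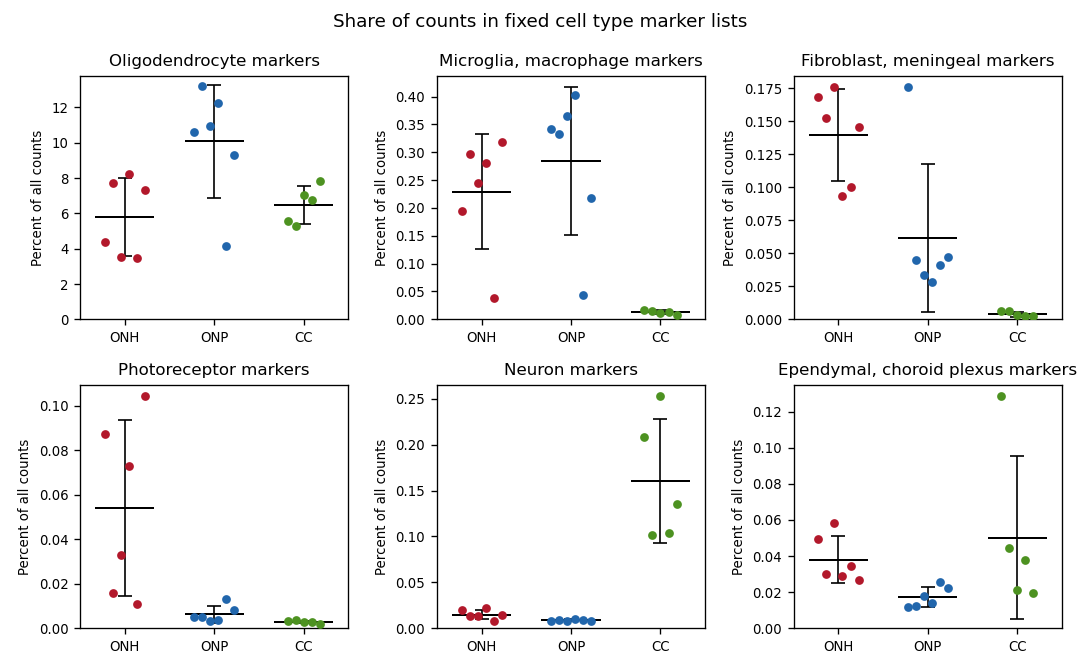
Percent of all counts (vertical axis, linear, from 0) taken by 6 lists of cell type markers in each library of ONH, ONP and CC (horizontal axis); points are libraries, long lines are means and bars are 1 SD. Microglial and fibroblast markers were lowest in the 5 CC libraries, neuron markers were highest there, and ONP replicate 5 lay at 4.15% of oligodendrocyte counts while the ONP mean was 10.1%.

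The comparison of ONH with ONP asked how astrocytes at the head of the nerve differ from those of the nerve behind it. The neuropeptide precursor Cartpt (ENSMUSG00000021647, chromosome 13: 99898489-99901091, GRCm38) averaged 1315 ± 736 CPM in ONH against 9.03 ± 13.8 in ONP, 142-fold (log2 fold change 7.16, SE 0.82, edgeR adjusted p = 0.000113). Its ONP mean rests largely on ONP replicate 5, at 37.1 CPM beside 1.42 to 5.06 in the other ONP libraries. Genes of the eye's pigment cells were higher too: the melanosome gene Mlana stood at 18.4 ± 15.0 CPM in ONH and had 3 counts over all ONP libraries, a ratio of 734 with a 95% counting interval of 251 to 3560. Genes of the oligodendrocyte lineage and of cholesterol synthesis were lower in ONH. Gpr17 (ENSMUSG00000052229, chromosome 18: 31942997-31949636), a receptor of committed oligodendrocyte precursors, fell from 150 ± 29.3 CPM in ONP to 46.1 ± 24.1 in ONH, a log2 fold change of -1.70 (SE 0.30, edgeR adjusted p = 0.00176). Dhcr7 (ENSMUSG00000058454, chromosome 7: 143823145-143848410), the enzyme of the last step of cholesterol synthesis, was 30.3 ± 11.6 CPM in ONH and 88.0 ± 25.7 in ONP, 2.90-fold lower (SE 0.23 on the log2 scale, edgeR adjusted p = 0.000732).

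The other genes with the largest increases in ONH were the serine protease gene Prss56 (72.4-fold), the melanosome gene Pmel (39.5-fold), the thyroxine carrier gene Ttr (38.9-fold) and the lactate transporter gene Slc16a8 (36.9-fold), with edgeR adjusted p-values from 0.00016 to 0.0164. The folds of Prss56, Ttr and Slc16a8 depend on 1 ONP library each. Prss56 was 7.83 CPM in ONP replicate 5 and at most 0.609 in the other ONP libraries. In ONP replicate 6 Ttr was 8.27 and Slc16a8 3.04 CPM, beside at most 1.56 and 0.310 in the others. Ttr was no longer past the test under limma voom (adjusted p = 0.182) or without a low-count filter (adjusted p = 0.0565). The largest decreases were in Cidea, a lipid droplet protein (3.97-fold), Susd5 (3.71-fold), Vxn (3.71-fold), Plpp4, a lipid phosphatase (3.23-fold), and Masp1, a protease of the lectin pathway of complement (3.23-fold). The rule took these genes only from those for which every ONH library lay on 1 side of every ONP library. There were 831 such genes in all, 5.18% of those tested, where chance gives 0.216%.

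**Figure D2:**
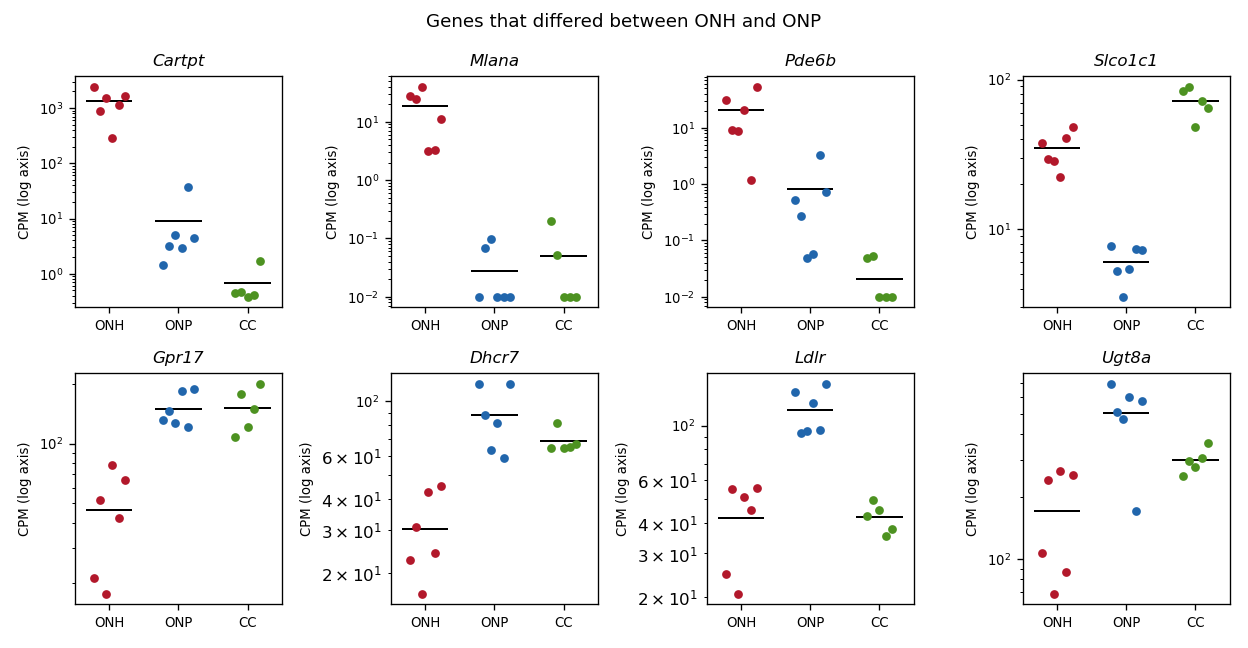
CPM on a log axis (vertical) of 8 genes in each library of ONH, ONP and CC (horizontal axis); points are libraries, lines are means, and libraries with 0 counts are drawn at 0.01 CPM. Cartpt, Mlana and Pde6b were highest in ONH, Slco1c1 was lowest in ONP, and Gpr17, Dhcr7, Ldlr and Ugt8a had lower means in ONH (46.1, 30.3, 42.0 and 170 CPM) than in ONP (150, 88.0, 116 and 504 CPM).

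Of the 22 measured genes of cholesterol synthesis, 20 fell in ONH and 2 were not past the test, and all 22 fell when adjusted over the list alone (median log2 fold change -1.03, camera adjusted p = 2.77e-15, adjusted p = 0.142 with an estimated correlation). Ldlr, which takes up low-density lipoprotein, was 42.0 ± 15.6 CPM in ONH and 116 ± 24.2 in ONP. The oligodendrocyte markers moved by a like amount, with 13 of 16 lower in ONH, 16 when adjusted over the list alone, and a median of -0.99 (camera adjusted p = 2.09e-07, adjusted p = 0.278 with an estimated correlation). Among them Ugt8a, which makes the myelin lipid galactosylceramide, was 2.96-fold lower and the lysophospholipase gene Enpp2 2.42-fold lower (edgeR adjusted p = 0.00557 and 0.011). Of the 10 precursor markers 9 fell, also when adjusted over the list alone (median -1.04, camera adjusted p = 2.09e-07, adjusted p = 0.142 with an estimated correlation), Sox10 by 1.45 on the log2 scale. With the oligodendrocyte marker level of each library as a covariate, an alternative chosen after the data were seen, 178 genes were higher and 259 lower in ONH. The covariate is the mean of the oligodendrocyte markers, so their mean change is near 0 by construction, and 0 of them were called. Of the other 2 lists, 5 cholesterol genes and 1 precursor gene remained past the edgeR test, which had 437 genes in both directions. Of the genes named above, 8 were then no longer past it (adjusted p from 0.0513 to 0.636). The log2 fold changes of Ugt8a, Enpp2 and Sox10 went from -1.57, -1.28 and -1.45 to -0.40, -0.18 and -0.68. Those of Plpp4, Susd5 and Masp1 went from -1.69, -1.89 and -1.69 to -1.49, -1.35 and -0.93, and those of Slc16a8 and Ttr from 5.20 and 5.28 to 4.24 and 3.34.

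Markers of retinal cells were higher in ONH. Of 14 measured photoreceptor markers 10 rose, 11 when adjusted over the list alone (median log2 fold change 3.54, camera adjusted p = 6.14e-07, adjusted p = 0.268 with an estimated correlation). The rod phosphodiesterase gene Pde6b was 20.7 ± 19.4 CPM in ONH and 0.833 ± 1.27 in ONP, and the phosducin gene Pdc 21.7 ± 19.6 and 1.28 ± 1.29. Of the 12 pigment cell markers 10 rose, also when adjusted over the list alone (median 4.56, camera adjusted p = 1.42e-05, adjusted p = 0.241 with an estimated correlation). So did 6 of 9 Muller glia markers (median 1.335, camera adjusted p = 0.000133, adjusted p = 0.142 with an estimated correlation). Of the 11 eye and optic stalk transcription factors 5 rose, 7 when adjusted over the list alone (median 1.30, camera adjusted p = 2.77e-05, adjusted p = 0.0847 with an estimated correlation). Fibroblast and meningeal markers had 3 of 12 members higher in ONH (median 0.89, camera adjusted p = 0.000144, adjusted p = 0.281 with an estimated correlation).

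Antigen presentation and interferon response genes were higher in ONH as a list, with 4 of 20 members past the test and 5 when adjusted over the list alone (median 0.85, camera adjusted p = 6.14e-07, adjusted p = 0.241 with an estimated correlation). The ubiquitin-like protein gene Isg15 was 2.84-fold higher (edgeR adjusted p = 0.0348), a call that ended without ONH replicate 3 or 5 or ONP replicate 2, 3 or 4 (adjusted p from 0.063 to 0.0775), or without a low-count filter (0.0614). The immunoproteasome gene Psmb8 was 1.97-fold higher (edgeR adjusted p = 0.0224), and 0.0619 without ONH replicate 3. Their log2 fold changes were 1.505 and 0.98. In the fewer libraries of mice of 7 to 8 weeks they were 1.5 and 1.025, but neither gene passed (edgeR adjusted p = 0.178 and 0.141). They were smaller with the oligodendrocyte covariate, at 1.03 and 0.70, and neither passed (adjusted p = 0.417 and 0.36). Cytosolic ribosomal protein genes were higher by a median of 0.30, with 6 of 32 past the test and 7 when adjusted over the list alone (camera adjusted p = 1.3e-06, adjusted p = 0.377 with an estimated correlation). Rplp2 and Rps16 rose by 0.57 and 0.57 on the log2 scale (edgeR adjusted p = 0.0302 and 0.0203), calls that ended without ONH replicate 1 or 3 and, for Rplp2, ONP replicate 1 or 6 (adjusted p from 0.0524 to 0.0812), and with the oligodendrocyte covariate at log2 fold changes of 0.32 and 0.36 (0.5 and 0.404). Rplp2 also ended without a low-count filter (0.0521). These genes are short, and fold changes fell with gene length across genes, which are not independent replicates (Spearman rho = -0.193 over 16041 genes). The shortest of 4 equal groups of genes, 204 to 2607 bases, had a median log2 fold change of 0.19. Respiratory chain genes, short as well, had 12 of 40 higher, with 16 higher and 1 lower when adjusted over the list alone (median 0.25, camera adjusted p = 5.27e-05, adjusted p = 0.44 with an estimated correlation).

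Of the 8 panel genes, edgeR called 1, Aqp4, between ONH and ONP. Gfap, the intermediate filament gene of astrocytes (ENSMUSG00000020932, chromosome 11: 102887336-102900912), was 12240 ± 4003 CPM in ONH and 15060 ± 6501 in ONP (edgeR adjusted p = 0.482). The glutamate transporter genes Slc1a2 and Slc1a3 had log2 fold changes of -0.51 and 0.51 (edgeR adjusted p = 0.211 and 0.196), the gap junction gene Gja1 0.31, the folate enzyme gene Aldh1l1 -0.13 and the optic stalk factor Pax2 0.60 (edgeR adjusted p from 0.363 to 0.716). Leaving out ONH replicate 5 took Slc1a2 past the test (adjusted p = 0.0421). Slc1a2 and Slc1a3 both passed with the replicate number as a block, which no label ties to shared mice (log2 fold changes -0.53 and 0.67, edgeR adjusted p = 0.0334 and 0.0416). Slc1a3 passed without ONP replicate 5 (adjusted p = 0.0301), under limma voom (0.0352), with the age band as a covariate (0.0459) and in mice of 7 to 8 weeks alone (log2 fold change 1.11, adjusted p = 0.00505), where Gja1 passed as well (0.66, adjusted p = 0.0237). Leaving out ONP replicate 5 turned the sign of Aldh1l1 (0.07) and of the astrocyte list. Aqp4, the water channel of astrocyte endfeet, fell by 1.03 on the log2 scale in ONH (SE 0.30, edgeR adjusted p = 0.024), and that call ended without ONH replicate 1, ONH replicate 3 or ONP replicate 6 (adjusted p = 0.0586, 0.0541 and 0.0562), and with the oligodendrocyte covariate at a log2 fold change of -1.32 (adjusted p = 0.053). Of 18 astrocyte markers 3 fell, also when adjusted over the list alone (median -0.23, camera adjusted p = 0.333). With the oligodendrocyte covariate 2 of them fell and the list was past camera (median -0.61, camera adjusted p = 1.9e-05, adjusted p = 0.3 with an estimated correlation). The forebrain factor Foxg1 had 1 count over the ONH libraries and 3 over the ONP libraries.

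Over all genes, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 1538 genes higher and 1469 lower in ONH, of which 550 and 522 differed at least 2-fold. The median log2 fold change of all genes was -0.01. Of the 25 gene lists 16 were past the camera test with a preset correlation of 0.01, and 0 with an estimated correlation. With 6 pools per region, differences near 2-fold may have been missed. In a simulation with 200 changed genes and 152 calls, 55% of 2-fold changes were recovered. With the 3007 calls here the adjusted threshold is less strict, so that share does not carry over directly.

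**Figure D3:**
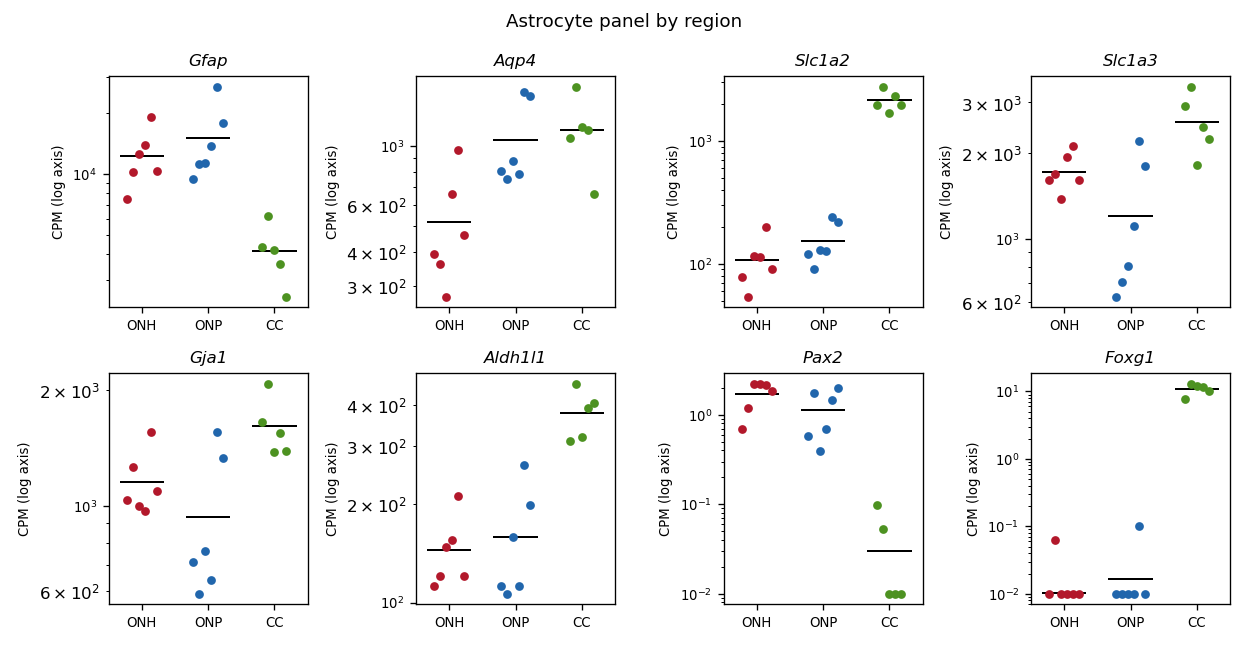
CPM on a log axis (vertical) of 8 astrocyte and region genes in each library of ONH, ONP and CC (horizontal axis); points are libraries, lines are means, and libraries with 0 counts are drawn at 0.01 CPM. Slc1a2 averaged 2148 CPM in CC against 108 in ONH and 155 in ONP, Gfap ran the other way with 4164 against 12240 and 15060, and Foxg1 was near 0 in both optic nerve regions.

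The comparison of ONH with CC set the nerve head against a tract outside the optic nerve. Transcripts for neurotransmitter handling were lower in ONH, among them the glutamate transporter gene Slc1a2 (ENSMUSG00000005089, chromosome 2: 102658659-102790784), at 108 ± 50.2 CPM against 2148 ± 421 in CC, a log2 fold change of -4.31 (SE 0.32, edgeR adjusted p = 1.09e-08). Gfap was 2.94-fold higher in ONH (SE 0.30 on the log2 scale, edgeR adjusted p = 0.000319). The homeobox gene Nkx6-1 (ENSMUSG00000035187, chromosome 5: 101658139-101664996) averaged 14.9 ± 5.51 CPM in ONH and had 0 counts in CC, at least 463-fold higher, taking 3 counts over the region as the floor. Tmem212 (ENSMUSG00000043164, chromosome 3: 27866066-27896368), a gene of ciliated ependymal cells, averaged 39.8 ± 16.6 CPM in CC and had 0 counts in ONH, at least 1730-fold lower. Foxg1 (ENSMUSG00000020950, chromosome 12: 49382660-49386861) averaged 10.9 ± 2.10 CPM in CC, 1420 times its level in ONH with a 95% counting interval of 254 to 56000.

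The other genes highest in ONH were Cartpt (1970-fold) and lens crystallins. Cryaa averaged 730 CPM in ONH with an SD of 1232, from 6.62 CPM in ONH replicate 4 to 3186 in ONH replicate 1, and 0.215 ± 0.171 in CC. Crybb2 and Cryba1 averaged 201 ± 313 and 139 ± 236 CPM in ONH, and Crygd, with 0 counts in CC, was at least 373-fold higher. That bound uses the ONH mean and leans on ONH replicate 1, as Crygd ran from 0.086 CPM in ONH replicate 4 to 50.1 in ONH replicate 1. Under limma voom Cryaa, Crybb2 and Cryba1 were not past the test (adjusted p = 0.0692, 0.0588 and 0.0789), and crystallin genes resemble each other in sequence, so how reads were divided among them is uncertain. Lowest in ONH beside Tmem212 were the glutamate receptor gene Grin2c, with 1 count in ONH and a ratio of 9040 (95% counting interval 1620 to 357000), the genes Ppp1r32, Sntn, a protein of the tip of motile cilia, and Nme9 (at least 1180-, 754- and 652-fold lower) and the interneuron transcript Dlx6os1 (at least 752-fold lower).

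Of the 20 genes of transmitter uptake and potassium handling 16 fell in ONH and 0 rose, also when adjusted over the list alone (median log2 fold change -2.57, camera adjusted p = 3.19e-09, adjusted p = 0.068 with an estimated correlation). The GABA receptor genes Gabrg1 and Gabra2 had log2 fold changes of -8.99 and -6.24 (edgeR adjusted p = 5.42e-09 and 5.78e-06). Neuron markers moved with this list, 12 of 17 lower in ONH and 2 higher (median -2.67, camera adjusted p = 6.1e-05, adjusted p = 0.0991 with an estimated correlation). The reactive astrocyte panel ran the other way, with 29 of 34 higher and 2 lower (median 3.30, camera adjusted p = 2.82e-11, adjusted p = 0.068 with an estimated correlation). Among them were the heat shock protein gene Hspb1 (77.2-fold) and the sphingosine kinase gene Sphk1 (49.0-fold). All 20 antigen presentation and interferon response genes rose (median 3.69, camera adjusted p = 2.82e-11, adjusted p = 0.0967 with an estimated correlation). The invariant chain gene Cd74 rose 98.2-fold and H2-Aa 77.0-fold, both genes of antigen-presenting cells, and H2 genes belong to a family of similar sequences. Microglial markers rose beside them, 17 of 18 (median 4.35, camera adjusted p = 4.36e-05, adjusted p = 0.398 with an estimated correlation). So did 14 of 17 vascular markers, while 2 fell (median 4.02, camera adjusted p = 0.00116, adjusted p = 0.314 with an estimated correlation) and all 12 fibroblast markers (median 5.02, camera adjusted p = 9.47e-05, adjusted p = 0.314 with an estimated correlation).

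All 12 neurogenic niche markers were lower in ONH than in CC (median -3.77, camera adjusted p = 4.02e-07, adjusted p = 0.132 with an estimated correlation). The interneuron factors Dlx1 and Sp8 had 2 counts and 1 count over the ONH libraries and averaged 51.5 ± 18.6 and 8.99 ± 6.27 CPM in CC. Of 10 measured forebrain transcription factors 8 fell, 9 when adjusted over the list alone (median -5.63, camera adjusted p = 2.21e-05, adjusted p = 0.068 with an estimated correlation), with Arx and Emx1 at 0 counts in ONH and at least 375- and 356-fold lower. Of 11 ependymal and choroid plexus markers 8 fell and 1 rose (median -2.35, camera adjusted p = 0.00535, adjusted p = 0.398 with an estimated correlation). Of 11 eye and optic stalk factors 9 rose and 1 fell (median 5.52, camera adjusted p = 0.000545, adjusted p = 0.068 with an estimated correlation). Pax2 went from 3 counts over the CC libraries to 1.72 ± 0.644 CPM, a ratio of 53.7 with a 95% counting interval of 18.4 to 260. Ribosomal protein genes rose, 22 of 32 (median 0.39, camera adjusted p = 1.72e-05, adjusted p = 0.398 with an estimated correlation), Rps16 by 0.83 and Rps6 by 0.80 on the log2 scale, where the shortest of the 4 length groups of genes had a median of 0.27 (Spearman rho = -0.172 across genes).

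In the remaining panel, Aldh1l1 and Aqp4 were 2.61- and 2.20-fold lower in ONH than in CC (edgeR adjusted p = 7.6e-05 and 0.00548). Slc1a3 and Gja1 had log2 fold changes of -0.58 and -0.48 (edgeR adjusted p = 0.0959 for both), and both passed the test in other settings. They did so with the libraries of the 2 regions alone (adjusted p = 0.00886 and 0.0171), in mice of 7 to 8 weeks alone (0.00671 and 0.0114), with the age band as a covariate (0.00383 and 0.0214), without ONP replicate 5 (0.0473 and 0.0463) and with the oligodendrocyte covariate (0.0279 and 0.0127). Gja1 also passed without ONH replicate 5 (0.0416). Of 18 astrocyte markers 8 fell and 2 rose, 9 and 3 when adjusted over the list alone (median -0.58, camera adjusted p = 0.0254, adjusted p = 0.577 with an estimated correlation, and adjusted p = 0.0586 without CC replicate 2). In all, edgeR called 4072 genes higher and 3787 lower in ONH, 2328 and 2260 of them at least 2-fold, with a median log2 fold change of 0.01 over all genes. The libraries of the 2 regions did not overlap for 5267 genes, 32.8% of those tested, where chance gives 0.433%. Of the 25 lists 20 were past the camera test and 0 with an estimated correlation. Pooling across the sexes was wholly confounded with the optic nerve against CC, since per the labels every ONH and ONP library was such a pool and no CC library was. Age was partly confounded with it, because all CC mice were 7 to 8 weeks old.

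The comparison of ONP with CC set the nerve behind the head against the same tract. Slc1a2 was 155 ± 60.8 CPM in ONP, 13.9-fold lower than in CC (SE 0.32 on the log2 scale, edgeR adjusted p = 6.92e-08), and Gfap was 3.62-fold higher (SE 0.30, edgeR adjusted p = 1e-04). The matrix protein gene Thbs4 (ENSMUSG00000021702, chromosome 13: 92751590-92794818), a thrombospondin, averaged 0.270 ± 0.420 CPM in ONP and 211 ± 50.2 in CC, 780-fold lower (log2 fold change -9.61, SE 0.75, edgeR adjusted p = 3.54e-08). Fam180a (ENSMUSG00000047420, chromosome 6: 35312668-35326141) averaged 48.0 ± 15.5 CPM in ONP and 0.200 ± 0.116 in CC, 230-fold higher (log2 fold change 7.84, SE 0.38, edgeR adjusted p = 1.35e-10). Pdzph1 (ENSMUSG00000024227, chromosome 17: 58878808-58991375) averaged 42.7 ± 10.1 CPM in CC and had 0 counts in ONP, at least 1700-fold lower.

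The Hedgehog ligand gene Dhh was 191-fold higher in ONP, the retinoic acid synthesis gene Aldh1a2 171-fold, the matrix Gla protein gene Mgp 135-fold and the microglial lectin gene Clec7a 128-fold (edgeR adjusted p from 4.98e-09 to 6.05e-05). The Aldh1a2 fold leans on ONP replicate 1, at 252 CPM beside 7.08 to 51.9 in the other ONP libraries. Dhh shares 25.2% of its exon length with an antisense gene, and Mgp was a member of the fibroblast list. Cryaa averaged 69.4 CPM in ONP with an SD of 127 (edgeR adjusted p = 0.0041, limma voom adjusted p = 0.269). Lower in ONP were Dlx6os1 (at least 691-fold), the cortical neuron factor Neurod6 (at least 469-fold), Grin2c (1070-fold) and Rprml, with 1 count in ONP and a ratio of 1500 (95% counting interval 269 to 59300).

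The reactive astrocyte panel had 26 of 34 members higher in ONP and 2 lower, 27 and 3 when adjusted over the list alone (median log2 fold change 2.68, camera adjusted p = 2.53e-11, adjusted p = 0.0395 with an estimated correlation). The proteoglycan gene Srgn rose 67.9-fold and Hspb1 43.4-fold. All 20 antigen presentation and interferon genes rose (median 2.77, camera adjusted p = 2.53e-11, adjusted p = 0.0708 with an estimated correlation), Cd74 89.0-fold and H2-Aa 57.4-fold. Microglial markers moved with both groups, 17 of 18 higher (median 4.45, camera adjusted p = 4.42e-06, adjusted p = 0.356 with an estimated correlation). Higher with them were 13 of 17 vascular markers, with 3 lower (median 3.52, camera adjusted p = 0.00359, adjusted p = 0.356 with an estimated correlation) and 11 of 12 fibroblast markers, 12 when adjusted over the list alone (median 4.83, camera adjusted p = 0.000765, adjusted p = 0.356 with an estimated correlation). Transmitter uptake and potassium handling genes fell, 16 of 20 and 17 when adjusted over the list alone (median -1.65, camera adjusted p = 7.99e-10, adjusted p = 0.0433 with an estimated correlation). Gabra2 had a log2 fold change of -6.79 and the serine and alanine transporter gene Slc7a10 one of -5.81, the latter with 17.9% of its exon length shared with Lrp3 on the other strand. Neuron markers fell beside them, 14 of 17 (median -3.82, camera adjusted p = 2.55e-08, adjusted p = 0.0395 with an estimated correlation).

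All 12 neurogenic niche markers were lower in ONP (median -3.30, camera adjusted p = 2.64e-09, adjusted p = 0.0774 with an estimated correlation). Sp8 was at least 359-fold lower, and Dlx5 had 1 count in ONP and a ratio of 1020 (95% counting interval 183 to 40200). Of 10 forebrain transcription factors 9 fell (median -6.45, camera adjusted p = 5.94e-09, adjusted p = 0.01 with an estimated correlation). Foxg1 had a ratio of 434 (95% counting interval 149 to 2100) and Emx1 of 981 (176 to 38800). The median of this list was -5.53 with genes near 0 counts set at their bounds. Ependymal and choroid plexus markers fell, 9 of 11 and 10 when adjusted over the list alone (median -4.87, camera adjusted p = 9.98e-05, adjusted p = 0.33 with an estimated correlation). Respiratory chain genes fell, 27 of 40 and 30 when adjusted over the list alone (median -0.36, camera adjusted p = 2.42e-08, adjusted p = 0.356 with an estimated correlation), Cox8a by 0.90 and Cox6c by 0.79 on the log2 scale, while the shortest of the 4 length groups of genes had a median of 0.11. Of 22 cholesterol synthesis genes 10 rose, 11 when adjusted over the list alone (median 0.41, camera adjusted p = 0.00133, adjusted p = 0.47 with an estimated correlation). Of 16 oligodendrocyte markers 6 rose (median 0.73, camera adjusted p = 0.00702, adjusted p = 0.533 with an estimated correlation). With the oligodendrocyte covariate the cholesterol list was not past camera (adjusted p = 0.0911).

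Of the remaining panel genes, Aldh1l1 was 2.39-fold, Slc1a3 2.13-fold and Gja1 1.73-fold lower in ONP than in CC (edgeR adjusted p = 0.000291, 0.00511 and 0.0129). With the oligodendrocyte covariate Gja1 had a log2 fold change of -0.55 (adjusted p = 0.0556). Pax2 had a ratio of 35.6 over CC (95% counting interval 12.2 to 173), and Aqp4 had a log2 fold change of -0.11 (edgeR adjusted p = 0.811), 0.06 without CC replicate 2. Of 18 astrocyte markers 9 fell and 3 rose, also when adjusted over the list alone (median -0.61, camera adjusted p = 0.0202, adjusted p = 0.533 with an estimated correlation, adjusted p = 0.0533 without CC replicate 2, and 0.143 with the oligodendrocyte covariate). In all, edgeR called 3018 genes higher and 2614 lower in ONP, 1777 and 1714 of them at least 2-fold, with a median log2 fold change of 0.04 over all genes. Libraries did not overlap for 3972 genes, 24.7% of those tested, where chance gives 0.433%. Of the 25 lists 17 were past the camera test and 4 with an estimated correlation, namely neuron markers, forebrain factors, transmitter uptake and the reactive panel.

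Some genes set 1 region apart from both others. In ONH 1093 genes were higher than in both other regions, led by Mlana, Cartpt, Prss56, Slc16a8 and the retinal opsin gene Rgr (313 ± 256 CPM in ONH, 9.23 ± 15.3 in ONP, 1.15 ± 1.11 in CC), and 1003 were lower, led by Vxn, Gpr17, Nxph1, Plpp4 and the cell adhesion gene Ntm. In ONP 224 genes were higher, led by Susd5, Ldlr, Aspg, Sema3d and Masp1, and 290 were lower, led by Crym, the thyroid hormone transporter gene Slco1c1, Bok, Nrsn1 and Gem. Slco1c1 (ENSMUSG00000030235, chromosome 6: 141524368-141570177) averaged 6.05 ± 1.62 CPM in ONP, 34.6 ± 9.49 in ONH and 71.9 ± 16.4 in CC, so that ONH was 5.70-fold above ONP (SE 0.22 on the log2 scale, edgeR adjusted p = 1.37e-05). Crym, which binds thyroid hormone, averaged 0.558 ± 0.449 CPM in ONP, 16.6 ± 17.3 in ONH and 46.0 ± 33.1 in CC (limma voom adjusted p = 0.0777 for ONH against ONP). With the oligodendrocyte covariate the counts fell to 140 higher and 231 lower in ONH and to 22 higher and 39 lower in ONP. Between ONH and ONP Rgr, Nxph1 and Sema3d then had log2 fold changes of 4.84, -1.12 and -0.93 and were no longer past the edgeR test (adjusted p = 0.0876, 0.0527 and 0.099). In CC 2117 genes were higher, led by Dlx6os1, Grin2c, Rprml, Neurod6 and Dlx1, and 2522 were lower, led by Cryaa, Fam180a, Dhh, Aldh1a2 and Mgp.

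Because both comparisons of a region share its libraries, these counts have a chance part. With no effect in any gene, each of 20 simulations gave 0 genes. That setting holds no true difference between regions, so it cannot show the part that shared libraries add beside true differences. Independent lists of the same sizes share 390, 347, 276, 250, 617 and 765 genes for ONH higher and lower, ONP higher and lower, and CC higher and lower, so the count of genes higher in ONP, 224, lay below that value. With the libraries of the region split between its comparisons, the counts ran from 76 to 778, 18 to 583, 2 to 38, 6 to 63, 1384 to 1434 and 1222 to 1497. Independent lists of the split sizes share 21.2 to 303, 5.26 to 302, 1.85 to 70.8, 10.7 to 97.9, 323 to 330 and 292 to 338 genes, so the ranges for CC lay wholly above theirs, those for ONH overlapped theirs, and those for ONP did not lie above theirs. The count of genes higher in ONP was 145 without ONP replicate 4, 148 without CC replicate 4, 350 without ONP replicate 5 and 420 under limma voom. Masp1 was above CC in ONP with an edgeR adjusted p of 0.0437, a call that ended without ONP replicate 1, 2, 3, 4 or 6 or any 1 of the CC libraries (adjusted p from 0.05 to 0.104). It ended too without a low-count filter, in mice of 7 to 8 weeks alone and with the age band (0.0575, 0.0572 and 0.11), where the log2 fold change was 1.04, 1.02 and 0.88 beside 1.05 in the fit of all libraries. It was smaller with the oligodendrocyte covariate, at 0.41 (0.318). Sema3d ended in the fewer libraries of mice aged 7 to 8 weeks alone (adjusted p = 0.0818 against ONH and 0.0546 against CC). There its log2 fold change was -1.02 for ONH against ONP and 0.88 for ONP against CC, beside -1.23 and 1.08 in all libraries.

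In CC 3 libraries were labelled female and 2 male. Ddx3y stood at 75.1 and 71.1 CPM in CC replicates 1 and 3, labelled female, at 0 in replicate 2, labelled female, and at 0 and 0.0598 in replicates 4 and 5, labelled male. Xist was 0 in replicates 1 and 3 and 1.96, 2.87 and 0.898 CPM in replicates 2, 4 and 5. These levels went against the labels of 4 of the 5 libraries, so the test by label did not compare the sexes. edgeR called 0 genes between the libraries labelled male and female, with 858 at an unadjusted p under 0.05, while DESeq2 called 26, and 2 genes were called by edgeR without CC replicate 2.

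Age was compared in ONH and ONP, with 6 libraries of mice aged 7 to 8 weeks and 4 of mice aged 11 to 12 weeks. Adcyap1r1, a neuropeptide receptor gene, Megf9 and the mitochondrially encoded gene mt-Nd4 were higher at 11 to 12 weeks, with log2 fold changes of 1.27, 0.89 and 0.86 (SE 0.17, 0.09 and 0.12, edgeR adjusted p = 0.031, 0.021 and 0.0439). Ctgf, the macrophage gene Ms4a7 and Mlana were lower, with log2 fold changes of -2.34, -3.10 and -3.27 (SE 0.30, 0.37 and 0.43, edgeR adjusted p = 0.031, 0.0304 and 0.031). Markers of other cells differed between these libraries too. Pigment cell markers held from 0.0419% to 0.0634% of the counts in the ONH libraries of 7 to 8 weeks and 0.0195% and 0.0149% in those of 11 to 12 weeks, and Mlana, a member of that list, had 3 counts over all ONP libraries. Microglial markers were at 0.0379% and 0.0443% in ONH and ONP replicates 5, aged 11 to 12 weeks, and at 0.280% and 0.402% in replicates 4 of the same age, the 2 libraries in which Xist was 0 CPM. These were the 6 genes called, against 2248 at an unadjusted p under 0.05 and 577 called by DESeq2. The count was 0 without any 1 of ONH replicates 1 to 5, 2 without ONP replicate 2, 54 without ONP replicate 4, 163 without a low-count filter, and 0 in ONH or ONP alone. The age difference was not shown to differ between ONH and ONP, since the edgeR interaction test called 0 genes, with 565 at an unadjusted p under 0.05, 27 called by DESeq2 and 11 by edgeR without a low-count filter.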

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

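Of the tests in this part, those on photoreceptor, pigment cell, lens and microglial covariation, the spread of the oligodendrocyte markers and the neuron markers in CC were chosen only after the results were seen, as were the fit with the oligodendrocyte marker level and the age splits by replicate number. The genes Rho, Dct, Mbp and Ctss were named after their values were seen.

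Single libraries lay far from the rest of their region on the log2 scale in 12 of 181 sets of a named gene, or of 3 library measures, within a region, where chance gives 9.05. In ONP replicate 5 Aspg stood at 88.7 CPM (36.1 to 47.3 in the other ONP libraries), Prss56 at 7.83 (0.132 to 0.609), Enpp2 at 535 (1590 to 2240), Ugt8a at 170 (472 to 697) and the microglial lectin gene Clec7a at 2.19 (12.3 to 27.5). In ONH replicate 5 Clec7a stood at 1.90 CPM (12.5 to 21.6 in the other ONH libraries) and Cd74 at 16.7 (69.1 to 148). In ONP replicate 1 Sphk1 stood at 41.8 CPM (4.74 to 8.57) and Bok at 15.4 (9.32 to 10.3), and in ONP replicate 4 Susd5 at 78.8 (40.9 to 45.9). In CC replicate 2 Slc7a10 stood at 228 CPM (151 to 164) and Dhcr7 at 81.9 (64.4 to 67.3).

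Photoreceptor and pigment cell genes were higher in ONH than in ONP (Rho at 149 against 11.8 CPM, Dct at 73.8 against 2.58), and so was the mean of the crystallin Cryaa (730 against 69.4 CPM), which was not past the edgeR test (adjusted p = 0.0812). No table argued against RNA of other eye tissue in the samples, which the pull-down of tagged ribosomes should remove. Photoreceptor and pigment cell RNA in ONH is a candidate explanation, since these markers correlated across the 6 ONH libraries with mean pairwise r of 0.845 and 0.587, which 0% of 1000 random lists matched on expression reached. Lens RNA carried over in dissection may account for the crystallins: the mean of 14 lens genes over the 6 numbers that ONH and ONP share, the only relation of this kind computed, gave Pearson r = 0.872 (exact permutation p = 0.0153, one-sided, smallest possible 0.00139) and Spearman rho = 0.829 (exact permutation p = 0.0292, one-sided), and it rests on the 2 numbers farthest from the median, as r was 0.537 without them. Libraries of a number also share an age band, and Cryaa was higher in the youngest mice than in the oldest. ONH replicates 1 to 3, the youngest, had 3186, 105.5 and 701 CPM, and replicates 4 and 5, the oldest, 6.62 and 21.35. The same ONP replicates had 323, 23.6 and 60.8 CPM, and 1.33 and 4.07. Replicates 6, of the age between, had 359 CPM in ONH and 3.24 in ONP. The permutation did not hold age fixed, so r cannot tell shared dissection from shared age. Covariation does not tell RNA of other cells from genes switched on together in ONH astrocytes, which stays open and was not tested.

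Oligodendrocyte, precursor and cholesterol synthesis genes were lower in ONH than in ONP. A smaller share of oligodendrocyte RNA in ONH may account for the markers, whose log2 fold changes had an SD of 0.25 around a median of -0.99 (Mbp at 21640 CPM in ONH and 37210 in ONP). Such a spread does not tell a smaller share from lower expression. The cholesterol and precursor lists had SDs of 0.34 and 0.33 around medians of -1.03 and -1.04. Whether oligodendrocyte RNA is the whole source of the cholesterol difference was not decided. With the oligodendrocyte marker level as a covariate the cholesterol list was past camera at the preset correlation (adjusted p = 3.36e-09), which would go against it. With an estimated correlation the list was not past camera (adjusted p = 0.213). Its median went from -1.03 (SD 0.34) to -0.56 (SD 0.29). Calls of single cholesterol genes fell from 20 to 5, all 5 among the 20. Their fold changes were smaller, and calls over all genes fell from 3007 to 437. Which of these ended the calls was not tested. The precursor list went from a median of -1.04 to -0.58 with 1 call. The covariate itself differs between the regions, so a difference of region in astrocytes stays open beside the share of oligodendrocyte RNA.

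Microglial, vascular and fibroblast genes were lower in CC than in both optic nerve regions. Neuron markers had a median log2 fold change of -3.82 (SD 2.72) in ONP against CC, so not every other cell type had less RNA in CC. The tracts may differ in their neurons. These markers therefore cannot decide whether less microglial, vascular and fibroblast RNA was carried over in CC. Microglial RNA in the optic nerve samples is a candidate explanation for the microglial part. Of its 18 markers 0 are in another list, and Ctss was 811 CPM in ONP and 15.7 in CC. The markers correlated with a mean pairwise r of 0.736 across the 12 optic nerve libraries, as deviations from the region means. Of 1000 random lists 0% reached this value. Random lists reached the r of vascular and neuron markers, 0.269 and 0.124, as rarely (0% and 0.2%). Such covariation was thus not particular to microglial markers, and it does not show why they were lower in CC. It was not computed without ONH and ONP replicates 5, where microglial markers took 0.0379% and 0.0443% of the counts. A difference between the tracts, in their cells or in their dissection, stays open and was not tested.

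Chance was weighed by regrouping the samples, with 100 splits each, the real one included. For genes past the test it can be excluded in all 3 region comparisons: 1 split of 100 gave as many genes for ONH against ONP (3007, highest other 767), 1 for ONH against CC (7859, highest other 5569) and 1 for ONP against CC (5632, highest other 4080). For lists past camera it was not excluded for ONH against CC, where 4 splits gave 20, the highest other also 20. That share lay under 0.05, but other splits reached the real count. Nor can chance be excluded for ONH against ONP (8 splits gave 16 or more, highest other 19) or ONP against CC (15 splits gave 17 or more, highest other 20). The median of the other splits was 9 of the 25 lists for ONH against ONP, 12 for ONH against CC and 11 for ONP against CC. For the genes that set a region apart 1 split of 100 gave as many in each of the 6 counts. These splits remove every difference between regions, so chance with no such difference can be excluded, while the part added by libraries shared between comparisons was not tested by them. The highest other splits had 0, 2, 0, 0, 1 and 0 genes for ONH higher and lower, ONP higher and lower and CC higher and lower, where the real counts were 1093, 1003, 224, 290, 2117 and 2522. For age 2 splits of 100, drawn in each region separately, gave 6 genes, the highest other also giving 6, so chance was not excluded. The share lay under 0.05, but another split reached the real count. That share also holds only if libraries that share a number are independent. The splits that give both regions the same numbers are 10, too few for a share under 0.05, with 6 genes in the real one and 1 in the highest other.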

How the results depend on the processing

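Fits without both optic nerve libraries numbered 5 and with the oligodendrocyte marker level as a covariate were chosen only after the data were seen. Of 136 named gene results, 98 kept their direction and side of the threshold under every alternative and 4 reversed under at least 1. The cause was not tested for any change listed here unless given. With the oligodendrocyte covariate ONH against ONP had 178 genes higher and 259 lower, genes apart from both other regions were 140 and 231 (ONH higher and lower) and 22 and 39 (ONP). The covariate differs between the regions, which can by itself lower the number of calls. How far it did so was not tested. The 2 regions alone gave 960 lower genes in ONH against ONP, and limma voom 420 genes higher in ONP than in both others. With an estimated correlation 0, 0 and 4 lists were past camera. DESeq2 called 26 genes for sex, 577 for age and 27 for the interaction. Without a low-count filter age had 163 genes and the interaction 11. Age had 0 genes in ONH alone and 0 in ONP alone, with fewer libraries. Without both libraries numbered 5 the region comparisons had 2963, 7872 and 5842 genes. Leaving out 1 library gave 145 to 350 genes higher in ONP (145 without ONP replicate 4, 148 without CC replicate 4, 350 without ONP replicate 5). It gave 0 to 2 for sex (2 without CC replicate 2), 0 to 54 for age (0 without any 1 of ONH replicates 1 to 5, 2 without ONP replicate 2, 54 without ONP replicate 4) and 0 for the interaction. It gave 1032 to 1858 higher and 997 to 1860 lower in ONH than ONP, and all other counts of genes and lists within 1.5 times. Reversed camera directions, as adjusted p, were astrocyte markers in ONH against ONP (0.967 at 7 to 8 weeks, 0.0572 to 0.898 leaving out 1 library, reversed without ONP replicate 5) and microglial markers there (0.0195 at 7 to 8 weeks, 0.214 without both libraries numbered 5, 0.0756 to 0.996 leaving out 1 library, reversed at 0.973, 0.996 and 0.0756 without ONH replicate 2, ONH replicate 3 or ONP replicate 5). With the covariate, oligodendrocyte (0.74), ependymal (0.175) and niche markers (0.829) reversed in ONH against ONP, Hedgehog genes in ONH against CC (0.931), and oligodendrocyte (0.695) and pigment cell markers (0.994) in ONP against CC. The oligodendrocyte reversals carry no information, since the covariate is the mean of those markers. Reversed log2 fold changes were Foxg1 in ONH against ONP, 1 and 3 counts in all (0.0689 under limma voom, 1.78 at 7 to 8 weeks, 1.27 without both libraries numbered 5, -2.28 to 1.16 leaving out 1 library), Aldh1l1 (0.00164 at 7 to 8 weeks, -0.27 to 0.0735 leaving out 1 library), Gja1 (-0.0836 with the covariate), and Aqp4 in ONP against CC (0.0788 with the covariate, -0.27 to 0.0617 leaving out 1 library). With the replicate block over shared numbers ONH against ONP had 1754 genes higher and 1627 lower, ONH against CC 3059 and 3206, and ONP against CC 2044 and 2269. Slc1a2 and Slc1a3 then passed in ONH against ONP (adjusted p = 0.0334 and 0.0416), Slc1a3 and Gja1 in ONH against CC (0.0324 and 0.0471), and Rplp2 did not in ONH against ONP (0.0543). As a hint from the data, not the design, same-numbered ONH and ONP libraries correlated at 0.0383 to 0.415, with 4 of 6 ONH and 5 of 6 ONP libraries best with their own number, against -0.148 to 0.0578 for ONH and CC and -0.0943 to 0.082 for ONP and CC, with 1 of 5 best. Depth limits genes at 0 to 3 counts over a region, whose folds are bounds or intervals.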

Other observations

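The genes named in this part were chosen only after their values were seen, while the lists and their tests were fixed earlier. Extracellular matrix genes went both ways in each comparison. In ONH 24 of 45 matrix and basement membrane genes were higher than in CC and 7 lower, 24 and 8 when adjusted over the list alone (median log2 fold change 1.22, camera adjusted p = 0.0238, adjusted p = 0.398 with an estimated correlation). The collagen gene Col18a1 rose by 5.58 and Sparc by 3.59 on the log2 scale, while the perineuronal net gene Hapln1 fell by 10.87 (edgeR adjusted p = 3e-10, 2.68e-08 and 1.4e-09). In ONP 21 were higher than in CC and 8 lower, 22 and 8 when adjusted over the list alone (median 0.91, camera adjusted p = 0.0982, and 0.0323 and 0.044 without ONP replicate 3 or 4). Between ONH and ONP 8 rose and 3 fell, 9 and 5 when adjusted over the list alone (median 0.48, camera adjusted p = 0.0198, adjusted p = 0.38 with an estimated correlation). Fibroblast markers moved with this list in all 3 comparisons, with median log2 fold changes of 0.89, 5.02 and 4.83. Hedgehog, Wnt and BMP genes went both ways. In ONH against ONP 5 of 26 were higher and 2 lower, 6 and 3 when adjusted over the list alone (median 0.33, camera adjusted p = 0.0724, and 0.0468 and 0.047 without ONH replicate 3 or ONP replicate 6). There were 7 and 8 in ONH against CC (median 0.17, camera adjusted p = 0.859) and 6 and 10 in ONP against CC, 9 and 11 when adjusted over the list alone (median -0.16, camera adjusted p = 0.281). The Hedgehog targets Gli1 and Ptch1 were higher in ONH than in ONP by 3.53 and 0.93 (edgeR adjusted p = 0.0101 and 0.00355).

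Immediate early and stress response genes were higher in ONH than in ONP, 9 of 21 (median 0.61, camera adjusted p = 0.000687, adjusted p = 0.351 with an estimated correlation), Dusp1 by 2.14 and Cyr61 by 2.01 on the log2 scale (edgeR adjusted p = 0.00787 and 0.0123). In ONH 15 of 21 were higher than in CC and 2 lower (median 1.67, camera adjusted p = 9.47e-05, adjusted p = 0.314 with an estimated correlation). In ONP 12 were higher and 1 lower (median 1.10, camera adjusted p = 0.00295, adjusted p = 0.433 with an estimated correlation). Glaucoma-associated genes had 4 of 24 higher and 1 lower in ONH against ONP (median 0.33, camera adjusted p = 0.00125, adjusted p = 0.142 with an estimated correlation). There were 14 and 2 in ONH against CC, 15 and 2 when adjusted over the list alone (median 0.85, camera adjusted p = 0.00187, adjusted p = 0.0961 with an estimated correlation) and 11 and 3 in ONP against CC (median 0.44, camera adjusted p = 0.0668, 0.0432 and 0.0471 without ONP replicate 3 or 4, and 0.0233 in mice of 7 to 8 weeks alone). Myoc, the gene of myocilin, fell by 5.06 in ONH against CC and by 3.40 in ONP against CC (edgeR adjusted p = 1.08e-05 and 0.000362). Engulfment genes had 2 of 18 higher and 2 lower in ONH against ONP, 4 and 3 when adjusted over the list alone, 7 and 5 in ONH against CC and 5 and 5 in ONP against CC (medians 0.04, 0.10 and 0.33, camera adjusted p = 0.426, 0.512 and 0.638). Among them the receptor gene Mertk fell by 2.01 and the bridging protein gene Mfge8 by 2.17 in ONH against CC, and the lectin gene Lgals3 rose by 5.91 (edgeR adjusted p = 3.69e-06, 7.53e-11 and 1.35e-09).

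In ONH against ONP, transmitter uptake and potassium handling genes had 9 of 20 lower (median -0.73, camera adjusted p = 0.000868, adjusted p = 0.278 with an estimated correlation). The reactive astrocyte panel had 9 of 34 higher and 2 lower, 10 and 3 when adjusted over the list alone (median 0.62, camera adjusted p = 0.00125, adjusted p = 0.278 with an estimated correlation, and 0.173 with the oligodendrocyte covariate). Vascular markers had 2 of 17 higher (median 0.07, camera adjusted p = 0.186), and neuron markers 3 of 17 higher and 1 lower (median 0.997, camera adjusted p = 0.115). Without ONH replicate 5 both lists were past camera (adjusted p = 0.0187 and 0.0482), as were vascular markers in mice of 7 to 8 weeks alone (0.0195). Ependymal and choroid plexus markers had 4 of 11 higher and 1 lower, 4 and 3 when adjusted over the list alone (median 0.21, camera adjusted p = 0.602), and niche markers 0 of 12 past the edgeR test (median -0.24, camera adjusted p = 0.426). Microglial markers had 0 of 18 past the edgeR test and a median of -0.18 and a mean of -0.06, while camera gave the direction up (adjusted p = 0.769, and 2.08e-05 with the oligodendrocyte covariate). In mice of 7 to 8 weeks alone camera gave the microglial markers the direction down (adjusted p = 0.0195). Forebrain factors had 2 of 10 higher, a median of -0.20 and a mean of -0.20, while camera gave up (adjusted p = 0.333).

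In ONH against CC, photoreceptor markers had 12 of 14 higher, 13 when adjusted over the list alone (median 6.96, camera adjusted p = 0.00095, adjusted p = 0.398 with an estimated correlation). Pigment cell markers had 9 of 12 (median 3.62, camera adjusted p = 0.00535, adjusted p = 0.398 with an estimated correlation), and Muller glia markers 4 of 9 with 1 lower (median 0.45, camera adjusted p = 0.23). Cholesterol genes had 11 of 22 lower and 1 higher (median -0.38, camera adjusted p = 0.0158, adjusted p = 0.577 with an estimated correlation, and 0.0643 with the oligodendrocyte covariate). Oligodendrocyte markers had 2 of 16 lower and 1 higher, 0 and 1 when adjusted over the list alone (median -0.40, camera adjusted p = 0.23) and precursor markers 3 of 10 lower and 1 higher (median -0.54, camera adjusted p = 0.137). Both were past camera in mice of 7 to 8 weeks alone (adjusted p = 0.018 and 0.0206). Respiratory chain genes had 16 of 40 lower and 5 higher (median -0.23, camera adjusted p = 0.0379, adjusted p = 0.674 with an estimated correlation), a call that ended without ONH replicate 2, 4 or 6 or CC replicate 2 or 3 (adjusted p from 0.0532 to 0.156) and in mice of 7 to 8 weeks alone (0.465). In ONP against CC, eye and optic stalk factors had 9 of 11 higher and 1 lower, 10 and 1 when adjusted over the list alone (median 4.15, camera adjusted p = 0.0044, adjusted p = 0.0708 with an estimated correlation). Precursor markers had 4 of 10 higher, 5 when adjusted over the list alone (median 0.61, camera adjusted p = 0.0183, adjusted p = 0.47 with an estimated correlation, and 0.335 with the oligodendrocyte covariate). Photoreceptor markers had 8 of 14 higher (median 3.31, camera adjusted p = 0.136), and ribosomal protein genes 5 of 32 higher (median 0.10, camera adjusted p = 0.0687, 0.00789 without CC replicate 2, and 0.0185 with the oligodendrocyte covariate). Muller glia markers had 2 of 9 higher and 4 lower (median -0.44, camera adjusted p = 0.281), and pigment cell markers 1 of 12 lower (median -0.49, camera adjusted p = 0.764).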
